A study of Rattus norvegicus with 12 samples.

How the data were processed

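Small RNA was sequenced from the serum of 7-week-old male Sprague-Dawley rats that had received one oral dose of vehicle, caffeine (180 mg/kg), dextromethorphan (200 mg/kg) or both drugs. Per the labels' protocols, in the combination group dextromethorphan followed caffeine by 1 h, and blood was taken 1 h after dextromethorphan. RNA came from 200 uL of serum with the miRNeasy Micro Kit, and libraries were made with the QIAseq miRNA kit, whose reverse transcription primer carries unique molecular indices. Whether these indices were used to collapse duplicate reads is not given in the sources used here. The design text gives 5 rats per group; 12 libraries, 3 in each of 4 groups, were analysed here.

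The deposited values are FPKM per mature microRNA, one column per library, made by the authors. Per the submitters' processing notes the tools were cutadapt 3.7, STAR 2.7.10a, featureCounts, Subread 2.0.1, DESeq2 1.20.0 and genome build rn6; the step each was used for is not given in the sources used here. In each column the FPKM times the microRNA length summed to the same constant, so a value is relative to the reads assigned to the listed microRNAs and not to all reads of the library. A rise in an abundant microRNA therefore lowers all others. Fractional counts in steps of 0.01, as arise when a read that matches several places is divided, accounted for 100% of the FPKM above 0 in each library within a tolerance of 0.0001 of a step, which gave the library totals. Between 65.4% and 75.0% of those fractional counts were whole numbers. Divided reads make the values of the let-7 family less certain, while the recovered counts of miR-200b-3p, miR-200c-3p and miR-429 were whole in all 12 libraries. Those of miR-192-5p, miR-194-5p, miR-122-5p, miR-1-3p, miR-206-3p and miR-133a-3p were not whole in every library, so divided reads enter these values too. Column names gave the group of each library but their numbers did not match the numbers in the sample titles, so libraries are named here as in the columns (ctrl, CAF, DEX and CAFDEX with a number).

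The table held 836 rows for 752 mature names. Of these names, 69 were listed at more than one locus, in 153 rows, and the copies were summed. This choice followed from the structure of the table and was made before any test; testing each row was added as an alternative. The pseudocount was 40 FPKM, set by rule as the median over libraries of the 10th percentile of values above 0, rounded. A name was tested when it was above 0 in at least 3 libraries with a mean of at least 80 FPKM, which left 366 microRNAs holding 99.99% of all FPKM; 203 names were at 0 in all 12 libraries. One read on a microRNA of 22 nucleotides was worth 17.3 FPKM in the deepest library and 113 FPKM in the shallowest, so the lowest values rest on few reads. Fold changes are on the log2(FPKM + 40) scale, which understates the change of microRNAs with low values.

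Differences were tested with limma 3.58.1 in R 4.3.3, as a linear model over the 4 groups with a mean-variance trend and empirical Bayes moderation (8 residual and 7.58 prior degrees of freedom). Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 366 microRNAs, with a threshold of 0.05. All tests are two-sided, and errors of log2 fold changes are standard errors (SE). The interaction contrast measures the departure of the combination from the sum of the single drugs on the log2 scale. Lists of microRNAs were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The fry test was run beside it; its p tests whether the members of a list move on balance in one direction and its mixed p whether they change in either direction, and neither compares a list with other microRNAs. Single quantities were compared by exact permutation over all 369600 assignments of the 12 libraries to 4 groups, or by two-sided exact permutation of 3 against 3 libraries, which cannot give a p below 0.1. Nothing in the labels says of each library that it came from a separate animal, so p-values measure the spread between these libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

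The comparisons, lists, pseudocount rule, filter and rule for naming were fixed before the data were examined; microRNAs named outside that rule were chosen after their values were seen. The rule named the 10 largest rises and falls among passing microRNAs whose mean level was above the median of those tested, the 5 smallest p-values in each direction where fewer than 5 passed, the 4 most abundant and all passing members of each list, and the 10 most abundant microRNAs. The lists covered erythrocyte, liver, striated muscle, brain, platelet, leukocyte, endothelium and smooth muscle, pancreas, epithelium of gut and kidney, the let-7 family, the miR-17 clusters, the Dlk1-Dio3 imprinted cluster, drug metabolism regulators and stress response. Members overlap between lists, and miR-192, miR-194 and miR-802 of the liver list are also abundant in gut and kidney. miR-486 and miR-215 were not analysed here, and the pancreas list had 1 tested member and so no list test. All rows were mature microRNAs, so the planned shares by RNA class came down to the share of the most abundant ones. Alternatives were another pseudocount, another filter, median-of-ratios scaling, quantile normalization, no trend, the haemolysis index as a covariate, the erythrocyte list left out, only the groups compared, and each library left out in turn. Added after the data were seen were each deposited row, limma voom on recovered counts, thinning to the smallest library, miR-191a-5p left out, and DEX2 and DEX3 left out. Host genes and sequence context were not analysed here.

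The fit was tested on simulated data for the comparison of dextromethorphan with control, in 20 simulations with 50 microRNAs changed. It recovered 23.0% of 356 changes of 2-fold, 69.7% of 287 of 4-fold and 82.6% of 345 of 8-fold, and 6.13% of 604 calls were false. A list of 14 microRNAs raised 2-fold was called in 20 of 20 simulations and an unchanged list in 0, with members simulated as independent.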

Results

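Mature microRNAs were measured by small RNA sequencing in rat serum after single oral doses, in 3 control libraries, 3 after caffeine, 3 after dextromethorphan (an antitussive that blocks NMDA receptors) and 3 after both drugs. The design asks how each drug given alone, and the pair given together, changes circulating microRNAs. Reads assigned to the listed microRNAs numbered 2.01e+06 ± 6.65e+05 in control libraries (SD, n = 3), 1.63e+06 ± 1.86e+05 after caffeine, 5.81e+05 ± 2.73e+05 after dextromethorphan and 9.86e+05 ± 2.06e+05 after both. Depth differed between the groups (exact permutation p = 0.00597, adjusted 0.0166 over 5 quantities), and the shallowest libraries were DEX3 with 403913 reads and DEX2 with 443564 reads.

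The most abundant microRNA was miR-191a-5p, which took 36.3% ± 2.79 of reads in control (SD, n = 3), 31.1% ± 4.49 after caffeine, 23.0% ± 3.86 after dextromethorphan and 25.6% ± 6.07 after both (exact permutation p = 0.0334, adjusted 0.0557, not passing). It was followed by miR-16-5p and by miR-122-5p, the main microRNA of hepatocytes, with 7.65% of reads on average. The 10 most abundant microRNAs together held 72.9% of reads in control, 73.1% after caffeine, 67.6% after dextromethorphan and 72.3% after both (exact permutation p = 0.0831, adjusted 0.104); for the 3 most abundant p was 0.287. The haemolysis index, the log2 ratio of the red-cell microRNA miR-451-5p to miR-23a-3p, was -7.53 ± 0.38 in control (SD, n = 3), -6.74 ± 0.35 after caffeine, -5.61 ± 0.74 after dextromethorphan and -5.99 ± 0.39 after both. It differed between groups (exact permutation p = 0.00662, adjusted 0.0166), and each treated group lay above control with p = 0.1, the smallest value that 3 against 3 allows. DEX2 and DEX3 had the highest indices, -5.12 and -5.25. The index rests on few reads of miR-451-5p, recovered counts of 38 in ctrl5 to 139.5 in ctrl3. For miR-23a-3p they were 2407 in DEX2 to 20111 in ctrl1, so miR-451-5p lay far below it in every library. A direct measure of haemolysis is not given in the sources used here, so a higher index does not by itself mean haemolysed serum.

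**Figure D1:**
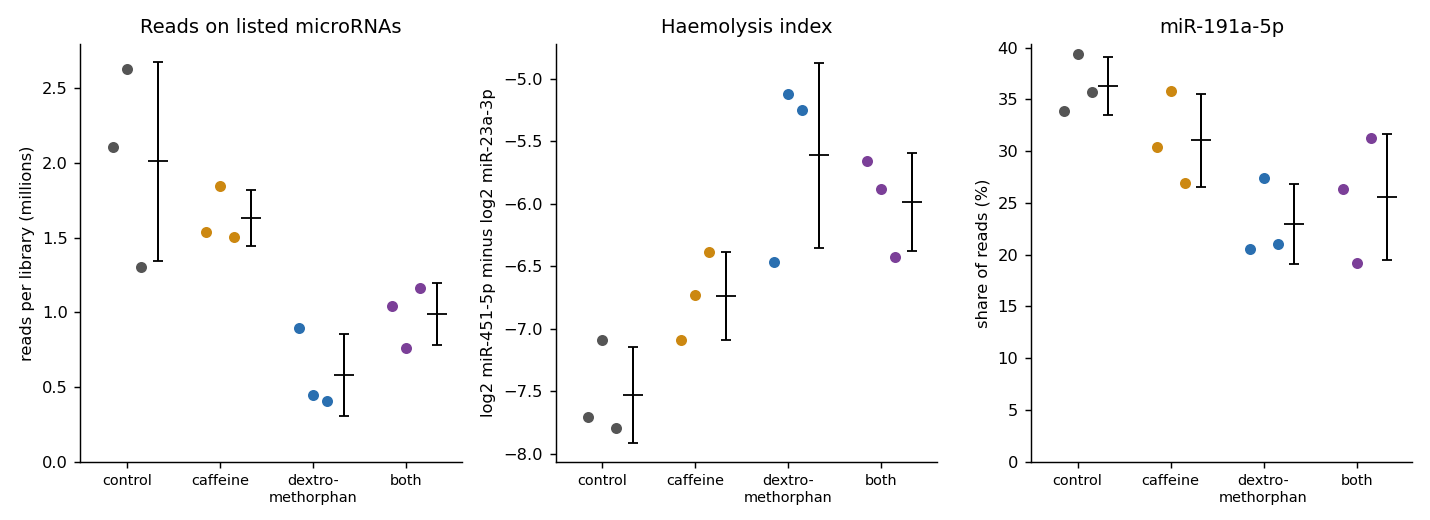
Reads on the listed microRNAs, haemolysis index (log2) and share of reads on miR-191a-5p (%) in each library, by group; points are libraries and bars are the mean ± SD of 3 libraries. Dextromethorphan libraries had the fewest reads, a mean of 5.81e+05 against 2.01e+06 in control, and the highest mean index, -5.61 against -7.53.

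After caffeine, microRNAs of striated muscle rose. miR-1-3p was 10.4-fold higher than in control (95% interval 4.51 to 23.8, n = 3 per group), miR-206-3p 9.54-fold (4.14 to 22.0) and miR-133a-3p 6.36-fold (3.34 to 12.1), each with a limma adjusted p of 0.00363 and with all 3 caffeine libraries above all 3 controls. miR-1b, which differs little in sequence from miR-1-3p, rose 11.7-fold. miR-122-5p rose 3.44-fold (1.94 to 6.11, adjusted p = 0.0137), from 1.34e+06 ± 7.91e+05 to 4.24e+06 ± 1.04e+06 FPKM (SD, n = 3). miR-1-3p and miR-133a-3p lie on chromosome 18 of the files' coordinates, at 2054945 to 2054966 and 2052492 to 2052513 on the minus strand, and the build in the submitters' notes is rn6.

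Of the striated muscle list 3 of 4 tested members rose, also when adjusted over the list alone, and miR-499-5p did not pass (log2 fold change 0.36). The list's camera adjusted p was 0.00153, and adjusted p = 0.408 with an estimated correlation. Of 27 members of the Dlk1-Dio3 imprinted cluster, a group of microRNA genes transcribed from the maternal allele, 6 rose, none fell and 21 did not pass; 11 rose adjusted over the list alone. Among them were miR-409a-3p, 4.08-fold higher (adjusted p = 0.0137), and miR-494-3p with a log2 fold change of 2.35 ± 0.53 (SE, adjusted p = 0.0141). The recovered count of miR-494-3p was 2 in each control library. The cluster had a camera adjusted p of 2.34e-05, and adjusted p = 0.433 with an estimated correlation. Of 20 members of the miR-17 clusters, 3 fell, over all microRNAs tested and adjusted over the list alone: miR-18a-3p (log2 fold change -1.66 ± 0.47, SE), miR-20a-5p (-1.27 ± 0.37) and miR-92a-3p (-1.02 ± 0.29). Their camera adjusted p was 0.00017, and adjusted p = 0.433 with an estimated correlation. In the liver list 3 of 12 rose (miR-122-5p, miR-192-5p and miR-802-5p; 4 adjusted over the list alone), and in the leukocyte list 2 of 19 rose, miR-150-5p by 1.43 ± 0.31 and miR-146a-5p by 1.18 ± 0.33 log2 units; neither list passed as a group (adjusted p = 0.236 and 0.723). 1 member each rose in the brain list (miR-218a-5p), the platelet list (miR-199a-3p), the endothelium and smooth muscle list (miR-10b-5p) and the epithelium list (miR-205), and no let-7 member passed (list adjusted p = 0.157, 0.236, 0.067, 0.106 and 0.204).

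In all, 29 of 366 microRNAs passed against control after caffeine, 25 higher and 4 lower, and 91 had an unadjusted p under 0.05. With median-of-ratios scaling the split was 12 higher and 7 lower, with quantile normalization 11 and 7 and without miR-191a-5p 16 and 4, and with the haemolysis index as a covariate 5 passed: miR-1-3p, miR-122-5p, miR-133a-3p, miR-199a-3p and miR-205. The count was 65 in a fit of the groups compared alone, 48 with voom, 11 without the low-value filter, 9 without the mean-variance trend and 18 without the erythrocyte list. It was 5 without ctrl1, 4 without ctrl3, 17 without CAF3, 10 without CAF4, 6 without CAF5, 15 without DEX3, 18 without CAFDEX2 and 44 without DEX1, the last 3 through the shared estimate of spread.

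**Figure D2:**
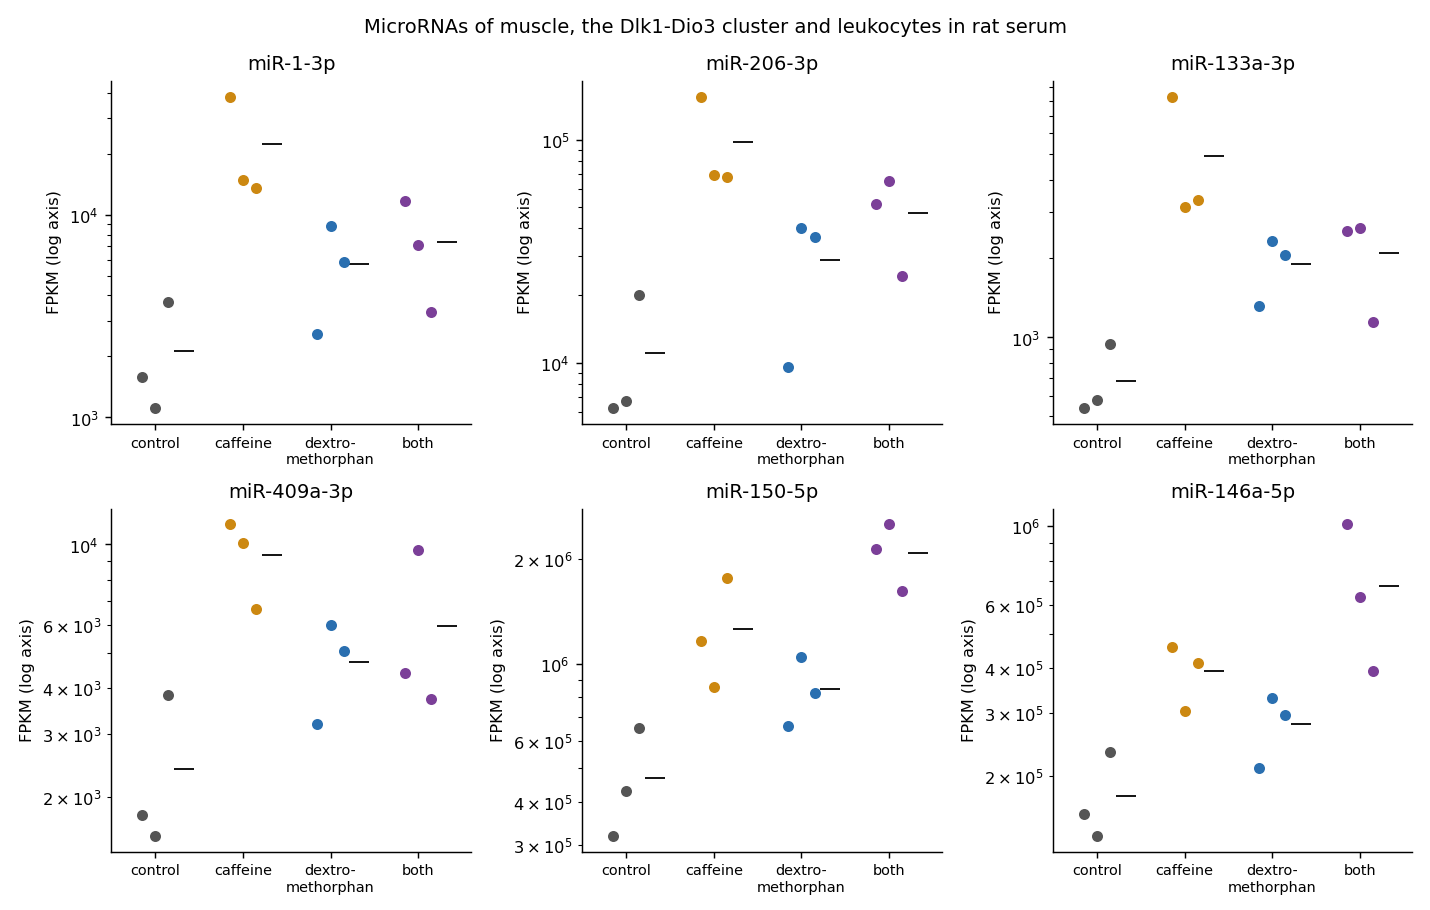
FPKM on a log axis of muscle microRNAs (miR-1-3p, miR-206-3p, miR-133a-3p), a Dlk1-Dio3 member (miR-409a-3p) and leukocyte microRNAs (miR-150-5p, miR-146a-5p); points are libraries, horizontal bars are means of 3 libraries. The caffeine libraries lie above control for each muscle microRNA, with miR-1-3p at 2.23e+04 FPKM on average against 2137, and miR-150-5p was highest after both drugs at 2.09e+06 FPKM.

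After dextromethorphan, microRNAs of epithelium and of the liver, gut and kidney rose. miR-194-5p was higher than in control by 3.39 ± 0.35 log2 units (SE, n = 3 per group; 95% interval 6.25-fold to 17.5-fold) and miR-192-5p 7.95-fold (4.93 to 12.8), both with a limma adjusted p of 1.9e-05. The epithelial miR-200 family rose with them: miR-429 by 9.37-fold (5.28 to 16.7, adjusted p = 5.28e-05) and miR-200b-3p by 8.93-fold (4.76 to 16.7, adjusted p = 0.00016). miR-375-3p, known from pancreatic islets and endocrine cells of the gut, rose 4.72-fold (2.78 to 8.02, adjusted p = 0.000561). For each of these 5 microRNAs all 3 dextromethorphan libraries lay above all 3 controls. DEX2 and DEX3 stood apart from the other libraries on the second principal component (12.74 and 10.75, the others at most 1.58), and without them the 17 passing members of the epithelium and liver lists went from a median log2 fold change of 2.702 to 1.71, with 7 of the 17 passing. miR-192-5p lies on chromosome 1 at 221634994 to 221635014 and 1 copy of miR-194-5p close by at 221634800 to 221634821, while miR-200b-3p and miR-429 lie on chromosome 5 at 173490160 to 173490182 and 173488342 to 173488363.

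Of 14 tested members of the epithelium list 10 rose, none fell and 4 did not pass; 11 rose adjusted over the list alone. Its camera adjusted p was 2.22e-05, and adjusted p = 0.242 with an estimated correlation. miR-200a-3p rose by 2.77 ± 0.42 log2 units (SE) and miR-141-3p 6.51-fold (3.43 to 12.3), while miR-30a-5p had a log2 fold change of 0.07. Some of the 10 rest on few reads. Recovered counts of miR-141-5p were 7, 7 and 9 in control libraries and 8, 9 and 8 after dextromethorphan. Those of miR-200a-5p were 3, 7 and 6 in control and 5, 14 and 7 after dextromethorphan. Of 12 members of the liver list 7 rose, over all microRNAs and adjusted over the list alone, among them miR-802-5p by 3.64 ± 0.53 and miR-122-5p by 1.64 ± 0.39 log2 units. Recovered counts of miR-802-5p were 3, 1 and 3 in control libraries and 18, 15 and 9 after dextromethorphan. The liver list had a camera adjusted p of 0.00319, and adjusted p = 0.242 with an estimated correlation. Red-cell microRNAs moved beside these groups: of 12 erythrocyte members miR-451-5p (log2 fold change 1.79 ± 0.33), miR-451-3p (2.15 ± 0.49) and miR-144-5p (1.64 ± 0.46) rose, 5 rose and 1 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.566). The abundant red-cell microRNA miR-16-5p had a log2 fold change of 0.23 (adjusted p = 0.412) and miR-92a-3p of -0.82 (adjusted p = 0.0608). In striated muscle 1 of 4 rose, miR-133a-3p by 1.43 ± 0.44 log2 units (3 adjusted over the list alone; list adjusted p = 0.37). In the endothelium and smooth muscle list 2 of 17 rose (9 adjusted over the list alone; adjusted p = 0.0654), and no let-7 or Dlk1-Dio3 member passed.

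Against control 44 of 366 microRNAs passed after dextromethorphan, 42 higher and 2 lower (miR-383-5p and miR-339-5p), and 118 had an unadjusted p under 0.05. With median-of-ratios scaling the split was 15 higher and 19 lower, with quantile normalization 13 and 17, and without miR-191a-5p 16 and 12; with the haemolysis index as a covariate 1 passed, miR-122-5p, whose log2 fold change was then 3.20 against 1.64 without it. The count was 25 in a fit of the groups compared alone, 29 after thinning, 26 without the low-value filter and 18 without the mean-variance trend. It was 16 without ctrl1, 13 without ctrl3, 22 without DEX2, 12 without DEX3, 74 without DEX1 and 67 without CAFDEX3. Of 34 calls with median-of-ratios scaling 17 were among the 44, and of 30 with quantile normalization 15. Without DEX2 and DEX3 together the median log2 fold change of all tested microRNAs went from 0.47 to 0.30.

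**Figure D3:**
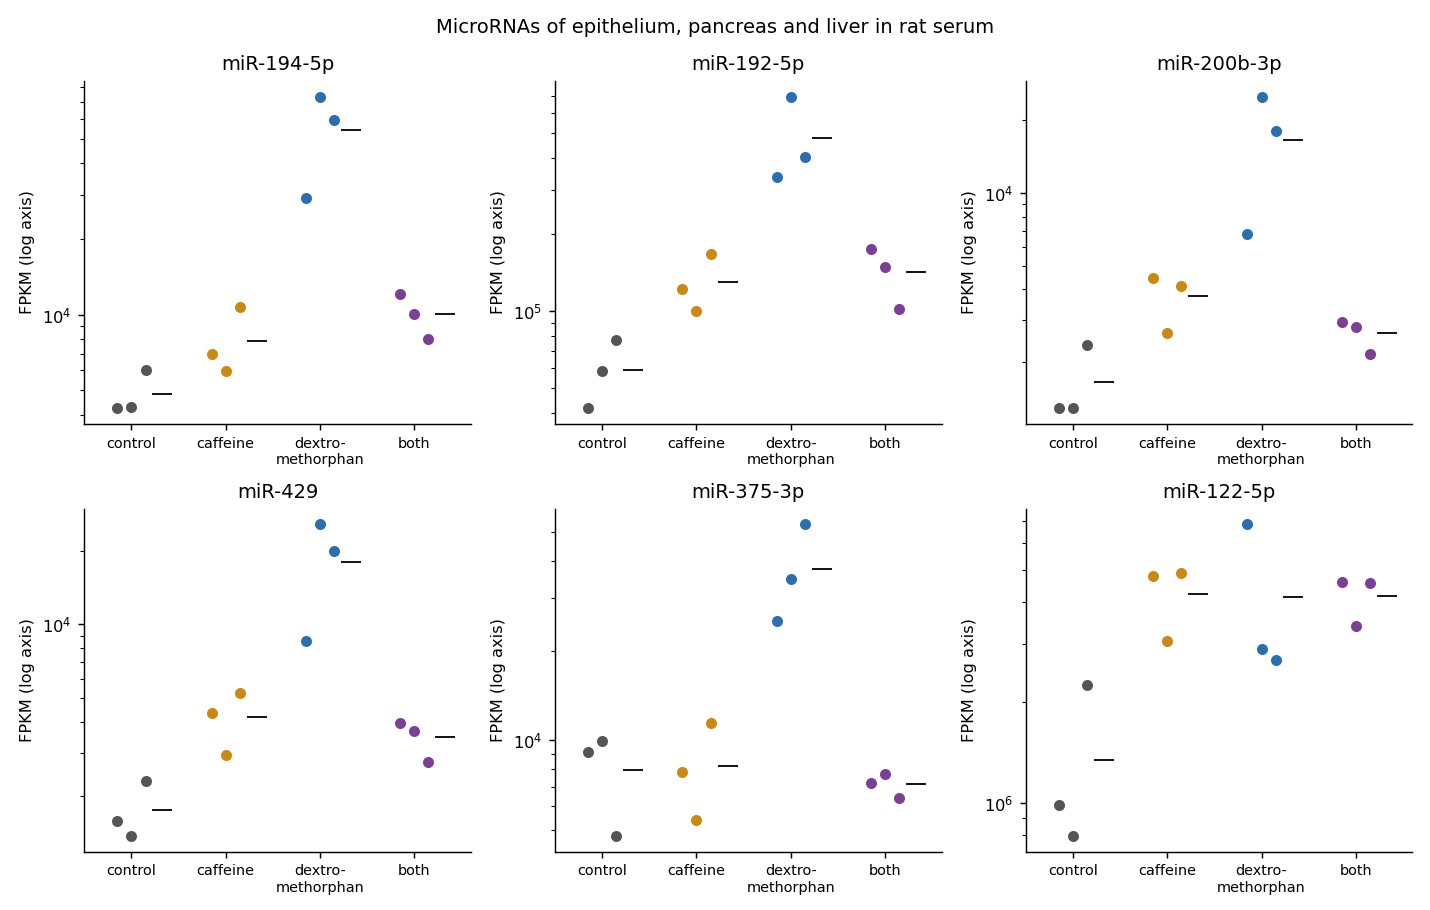
FPKM on a log axis of miR-194-5p, miR-192-5p, miR-200b-3p, miR-429, miR-375-3p and miR-122-5p; points are libraries, horizontal bars are means of 3 libraries. miR-194-5p averaged 5.41e+04 FPKM after dextromethorphan against 4845 in control and 1.01e+04 after both drugs, whereas miR-122-5p was at 4.14e+06 and 4.18e+06 FPKM in those treated groups.

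After both drugs, microRNAs of leukocytes were among the largest rises against control. miR-150-5p, abundant in lymphocytes, was 4.61-fold higher (95% interval 2.91 to 7.31, n = 3 per group, limma adjusted p = 0.00118). miR-155-5p rose 3.72-fold (2.18 to 6.35, adjusted p = 0.0074) and miR-146a-5p by 1.89 ± 0.33 log2 units (SE, adjusted p = 0.0039), both induced in activated immune cells, and miR-122-5p rose 3.43-fold (adjusted p = 0.0156). The largest falls by the naming rule were miR-20a-5p, whose log2 fold change was -1.90 ± 0.37 (SE, adjusted p = 0.0074), and miR-652-3p with -1.71 ± 0.41. The epithelial microRNAs miR-200b-3p and miR-375-3p had log2 fold changes of 0.71 and -0.09 and did not pass.

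Of 19 leukocyte members 3 rose and miR-223-5p fell (4 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0829). In striated muscle 2 of 4 rose, miR-206-3p by 2.20 ± 0.57 and miR-133a-3p by 1.52 ± 0.44 log2 units (3 adjusted over the list alone; list adjusted p = 0.0829). Of the miR-17 clusters 4 of 20 fell (5 adjusted over the list alone), including miR-18a-5p (log2 fold change -1.25 ± 0.33) and miR-92a-3p (-1.36 ± 0.29); the list's camera adjusted p was 0.0116, and adjusted p = 0.685 with an estimated correlation. Of the Dlk1-Dio3 cluster miR-485-3p alone of 27 members rose (none adjusted over the list alone), with a camera adjusted p of 0.0168, and adjusted p = 0.685 with an estimated correlation. In the liver list 3 of 12 rose (4 adjusted over the list alone; adjusted p = 0.234), and no epithelium member passed. Among erythrocyte members miR-451-5p rose by 1.12 ± 0.33 log2 units, and miR-185-3p and miR-92a-3p fell. Of 17 brain members miR-128-3p and miR-383-5p fell, and neither the brain nor the erythrocyte list passed (adjusted p = 0.234 and 0.812).

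Against control 40 of 366 microRNAs passed after both drugs, 24 higher and 16 lower, and 103 had an unadjusted p under 0.05. With median-of-ratios scaling the split was 19 higher and 25 lower, with quantile normalization 17 and 21, and without miR-191a-5p 12 and 27; with the haemolysis index as a covariate 1 passed, miR-122-5p, whose log2 fold change was then 3.03 against 1.78 without it. The count was 13 without the low-value filter and 17 without the mean-variance trend. It was 3 without ctrl1, 8 without ctrl3, 4 without CAFDEX2, 8 without CAFDEX3 and 20 without CAF5, and 60 without DEX2 and DEX3 together.

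Both drugs were compared with caffeine to show what dextromethorphan added. With limma 0 of 366 microRNAs passed, 22 had an unadjusted p under 0.05, and voom on the recovered counts also gave 0; the smallest adjusted p was 0.786. The smallest unadjusted values were those of miR-155-5p, with a log2 fold change of 1.09 ± 0.36 (SE, n = 3 per group), and miR-3559-5p, with -0.85 ± 0.29. miR-1-3p had a log2 fold change of -1.60 ± 0.57, an interval of 0.144 to 0.761 as a ratio, and miR-133a-3p of -1.15 ± 0.44. As a group leukocyte microRNAs were higher (median log2 fold change 0.25, camera adjusted p = 0.000347, and adjusted p = 0.543 with an estimated correlation). Striated muscle was lower (median -1.11, adjusted p = 0.0165, and adjusted p = 0.543 with an estimated correlation; 2 of 4 fell adjusted over the list alone). The Dlk1-Dio3 cluster was also lower (median -0.45, adjusted p = 0.0399, and adjusted p = 0.911 with an estimated correlation).

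Both drugs were compared with dextromethorphan alone to show what caffeine added. Some of the microRNAs that rose after dextromethorphan alone were lower after both: miR-194-5p had a log2 fold change of -2.34 ± 0.35 (SE, n = 3 per group, limma adjusted p = 0.00157), miR-375-3p of -2.33 ± 0.36 (0.00157), miR-200b-3p of -2.45 ± 0.43 (0.00305) and miR-429 of -2.24 ± 0.39 (0.00305). miR-192-5p and miR-802-5p fell too, by 1.71 ± 0.32 and by 2.51 ± 0.53 on the log2 scale. miR-150-5p was the 1 microRNA that rose, 2.48-fold (1.56 to 3.93, adjusted p = 0.0244). Of 14 epithelium members 6 fell (9 adjusted over the list alone; camera adjusted p = 5.33e-06, and adjusted p = 0.211 with an estimated correlation). Of 12 liver members 3 fell (5 adjusted over the list alone; adjusted p = 0.00144, and adjusted p = 0.211 with an estimated correlation). The leukocyte list, with 1 of 19 higher (3 adjusted over the list alone), had an adjusted p of 0.00497, and adjusted p = 0.577 with an estimated correlation. The Dlk1-Dio3 cluster, median log2 fold change 0.34 with no member passing, had an adjusted p of 0.00144, and adjusted p = 0.577 with an estimated correlation. In all 13 of 366 microRNAs passed, 1 higher and 12 lower, with 59 at an unadjusted p under 0.05; the split was 6 and 11 with median-of-ratios scaling, 6 and 11 with quantile normalization and 3 and 12 without miR-191a-5p, and 16 passed with the haemolysis index as a covariate. The count was 24 without DEX1, and 0 by limma without DEX2 and DEX3 together, where 56 had an unadjusted p under 0.05.

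The interaction asked whether the effect of both drugs differed from the sum of their separate effects. For 17 of 366 microRNAs it did, and for each of the 17 the combination was lower than the sum. miR-200b-3p departed by -3.64 ± 0.60 log2 units (SE, n = 3 per group), miR-429 by -3.48 ± 0.55, miR-194-5p by -3.01 ± 0.49 and miR-192-5p by -2.87 ± 0.46, each with a limma adjusted p of 0.00145. Muscle microRNAs departed in the same direction, miR-1-3p by -3.03 ± 0.80 (adjusted p = 0.0415) and miR-133a-3p by -2.58 ± 0.62 (0.0259). Of the 17 microRNAs 14 had risen with dextromethorphan alone and 7 with caffeine alone. The contrast subtracts both single-drug groups, so the same libraries enter both tests, and this overlap and the common sign were favoured in advance. A shift shared by all treated libraries against control also gives a negative departure, which the contrast cannot tell from an effect of the pair. Of 14 epithelium members 5 passed (9 adjusted over the list alone; camera adjusted p = 3.95e-06, and adjusted p = 0.249 with an estimated correlation), of 12 liver members 4 (6 adjusted over the list alone; adjusted p = 0.00372, and adjusted p = 0.249 with an estimated correlation) and of 4 muscle members 2 (3 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.344 with an estimated correlation). The endothelium and smooth muscle list was negative as a group with no member passing (3 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.559 with an estimated correlation). The miR-17 clusters, with a median of 0.01, were tested higher than the other microRNAs (adjusted p = 0.033, and adjusted p = 0.559 with an estimated correlation), and the median of all tested was -0.39. The count of 17, with 78 at an unadjusted p under 0.05, was 8 with median-of-ratios scaling, 7 with quantile normalization, 9 without the low-value filter, 11 without miR-191a-5p and 7 with the haemolysis index as a covariate, among them miR-194-5p, miR-429 and miR-200b-3p and, not among the 17, miR-122-5p (-2.59). It was 10 without ctrl1, 8 without ctrl3, 8 without CAF3, 11 without CAF5, 8 without DEX3, 8 without CAFDEX6 and 38 without CAFDEX3. Without DEX2 and DEX3 together it was 20, of which 6 were among the 17.

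**Figure D4:**
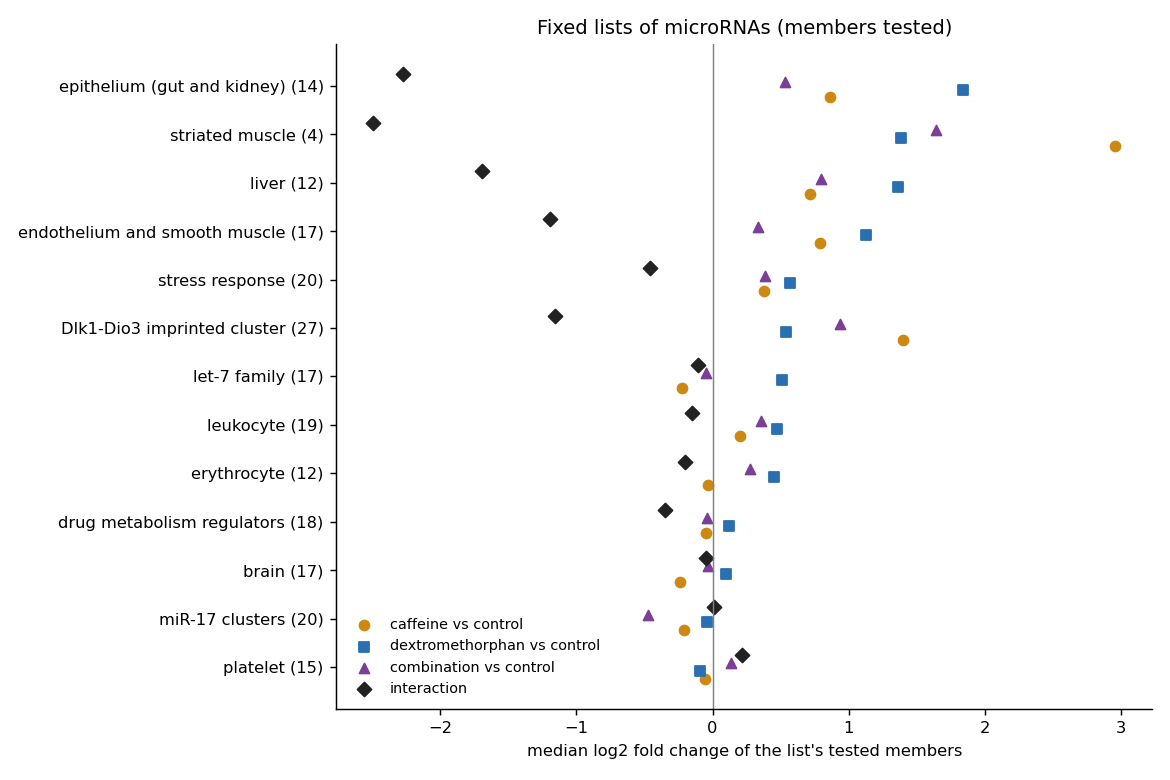
Median log2 fold change of the tested members of each list, for the 3 comparisons with control and the interaction; the number of members is in brackets and each symbol is 1 median. The epithelium list had a median of 1.84 after dextromethorphan and 0.53 after both drugs, and striated muscle 2.96 after caffeine and 1.65 after both.

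Over all 4 groups 42 of 366 microRNAs differed (limma F test), and 116 had an unadjusted p under 0.05; miR-194-5p had the smallest adjusted p, 0.000124. The count was 18 without ctrl1, 18 without ctrl3, 27 without CAF5, 26 without DEX3, 27 without CAFDEX2 and 71 without DEX1, and 16 with the haemolysis index as a covariate. The median log2 fold change of all tested microRNAs was 0.19 after caffeine, 0.47 after dextromethorphan and 0.24 after both; median-of-ratios scaling set these to -0.04, 0.11 and 0.08, and quantile normalization to -0.11, 0.03 and 0.03. For both drugs against dextromethorphan it was -0.24, and -0.00 with median-of-ratios scaling; for the interaction it was -0.39, and 0.10 with that scaling. Changes above are on the deposited scale, without this shift taken off.

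None of the 19 camera calls held with an estimated correlation. By fry, which asks whether the members move on balance in one direction, the Dlk1-Dio3 cluster and striated muscle passed after caffeine (adjusted p = 0.0428 and 0.01), and epithelium and liver passed after dextromethorphan (0.00102 and 0.000337). Epithelium and liver also passed for both drugs against dextromethorphan (0.00715 and 0.00629) and for the interaction (0.00482 and 0.00308), where striated muscle passed as well (0.042). No list passed by fry for both drugs against control. Median and camera test differed in sign for the brain list after dextromethorphan (median 0.10, tested lower), and for erythrocyte and platelet after both drugs (0.27 and 0.14, tested lower). They differed too for the brain, let-7, leukocyte, drug metabolism and stress lists in the interaction, for the brain, platelet and stress lists in both drugs against dextromethorphan, and for these and the miR-17 clusters in both drugs against caffeine, each with a negative median and tested higher; none of these passed by camera.

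Log2 fold changes against control were correlated between the 3 treatments, which share the 3 control libraries. miR-122-5p, miR-133a-3p, miR-139-5p, miR-192-5p, miR-224-5p and miR-378a-5p rose in all 3 treated groups, and no microRNA fell in all 3. Across microRNAs, which are not independent replicates, log2 fold changes of caffeine and of both drugs had r = 0.822 and covariance 0.579, caffeine and dextromethorphan r = 0.653 and covariance 0.476, and dextromethorphan and both drugs r = 0.663 and covariance 0.516. Unchanged groups simulated against the same controls gave r = 0.499, 0.504 and 0.500 in that order, at most 0.605, 0.627 and 0.600 in 100 simulations, and covariances of 0.124, 0.125 and 0.125. Each microRNA was simulated as independent noise, while real ones move together, with an estimated correlation of 0.328 in the erythrocyte list. The highest simulated values may therefore lie too low, and the jackknife error of r was 0.106 to 0.147. Caffeine and both drugs shared 12 rises, where independent lists would share 1.64; caffeine and dextromethorphan shared 9 (2.87) and dextromethorphan and both drugs 10 (2.75). The 3 controls cannot be split to leave 2 in each part, so part of the excess may come from the shared controls. Each treated group also had a lower mean read total and a higher mean haemolysis index than control. Whether these enter the correlations was not tested.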

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

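Chosen after the results were seen were the tests of scaling, of the haemolysis index, of single caffeine libraries, of shared reads, of miR-191a-5p and of other groupings of the libraries; the 2 thinning tests were written down before their results.

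The effect of dextromethorphan differed between libraries with and without caffeine for 17 microRNAs by the interaction test, which is what marked them for a closer look. The departures on the log2 scale were -4.97 for miR-802-5p, -3.70 for miR-1b, -3.64 for miR-200b-3p, -3.48 for miR-429, -3.20 for miR-200b-5p, -3.12 for miR-200a-3p, -3.03 for miR-1-3p, -3.01 for miR-194-5p, -2.87 for miR-192-5p, -2.72 for miR-141-3p, -2.58 for miR-133a-3p, -2.41 for miR-192-3p, -2.38 for miR-375-3p, -1.73 for miR-193a-5p, -1.73 for miR-199a-3p, -1.71 for miR-224-5p and -1.39 for miR-152-3p. The largest, that of miR-802-5p, rests on recovered counts of 3, 1 and 3 in control libraries and 7, 2 and 3 after both drugs. Control counts of miR-192-3p were 4, 7 and 4. Of 100 assignments of the 12 libraries to the 4 groups, the real one included, 1 gave as many interaction calls (17, against at most 10 in the others) and 1 gave as many microRNAs differing over all groups (42, against at most 38); the margin is narrow for the second.

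The 17 epithelial and liver microRNAs that rose with dextromethorphan had a median log2 fold change of 2.702 (median SE 0.44). Thinning every library to the smallest total left a median of 2.705 over 20 thinnings (2.46 to 3.01). Thinning keeps the expected share of each microRNA, so it cannot decide whether what made these libraries shallow raised the members. Median-of-ratios scaling left 2.297. It moves all microRNAs of a library by 1 factor and took the median of all tested from 0.47 to 0.11. These members, picked for rising, rose beyond that common shift, and other effects of the makeup of the libraries stay undecided. If red-cell RNA were the whole cause, both drugs, with 0.659 of the index rise at least, would bring a median of 1.78. It was 0.579 (median SE 0.44). The members were picked for rising after dextromethorphan, which raises the 1.78, so the test cannot decide. Over the whole lists the medians after dextromethorphan and after both drugs were 1.84 and 0.53 for epithelium, and 1.36 and 0.80 for liver. A part of red-cell RNA stays open too. With the index as a covariate the rise after dextromethorphan was 1.749 (median SE 0.80) with 1 of 17 passing. Calls were lost to a lower estimate and to errors 1.57 to 2.01 times larger, as the index follows the groups (R squared 0.770). The median difference of both drugs from dextromethorphan was -1.71 without and -1.508 with the covariate (median SE 0.43), with 8 of 9 falls still passing. The mean indices of these groups, -5.99 and -5.61, lay close, so the covariate could change little. Members picked for high values after dextromethorphan also favour a fall, so the test does not decide on red-cell RNA. Over the whole lists the medians without the covariate were -1.37 for epithelium and -1.05 for liver. Without DEX2 and DEX3 the median rise was 1.71 (median SE 0.48) with 7 of the 17 passing, and the median difference of the combination from dextromethorphan was -0.85 with none passing, so the effect of the drug remains an untested candidate explanation beside whatever sets those libraries apart.

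The 3 muscle microRNAs that rose with caffeine had a median log2 fold change of 3.25 (median SE 0.57). A single library is argued against: the whole muscle list of 4 kept a median of at least 2.541 when any caffeine library was left out, the lowest without CAF3. Reads shared among miR-1-3p, miR-1b and miR-206-3p do not account for miR-133a-3p, whose sequence is unrelated and whose log2 fold change was 2.669. With the haemolysis covariate their median was 2.679 (median SE 0.66), and 2 of 3 passed. These 3 were picked for rising after caffeine, and the index follows the groups (R squared 0.770). The test therefore does not decide on red-cell RNA. A release of these microRNAs after caffeine is a hypothesis that these tests leave open, and handling of the animals was not tested.

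Of the 113 calls in the 3 comparisons with control, 91 or 80.5% were rises. Whether the makeup of the libraries accounts for this excess stays open. Without miR-191a-5p and with the rest rescaled 50.57% of calls were rises. The lower share of miR-191a-5p in treated libraries (a difference that did not pass, exact permutation adjusted p = 0.0557) fixes the direction of that drop. With median-of-ratios scaling 47.4% were rises. That scaling takes off most of the common upward shift of the treated libraries, which favours fewer rises as well. Without miR-191a-5p the drop came mainly from dextromethorphan (16 of 28 calls) and both drugs (12 of 39). Caffeine then kept 16 rises of 20 calls (80.0%, against 86.2% with miR-191a-5p). With median-of-ratios scaling caffeine shared in the drop, with 12 rises of 19 calls (63.2%), and with quantile normalization it had 11 of 18 (61.1%). After thinning 82.04% were rises (78.8% to 85.9% over 20 thinnings), which argues against unequal read numbers alone. Thinning keeps expected shares, so it cannot decide whether what made the libraries shallow plays a part. The design cannot say whether miR-191a-5p fell or the others rose.

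Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real grouping and the highest other split gave 29 and 0 calls for caffeine against control, 44 and 2 for dextromethorphan, 40 and 0 for both drugs, 0 and 1 for both drugs against caffeine, and 13 and 3 for both drugs against dextromethorphan.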

How the results depend on the processing

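Voom, thinning, the leaving out of miR-191a-5p, of DEX2 with DEX3 and the testing of each deposited row were added after the data were seen. The causes of the changes below were not tested unless stated. No named microRNA that passed changed direction, except 2 log2 fold changes with the haemolysis covariate (miR-140-3p, dextromethorphan vs control: -0.1486, 0.94 before; miR-144-5p, dextromethorphan vs control: -0.0195, 1.64 before). With it 24 of 116 calls of named microRNAs held, 90 were lost and 2 reversed. Median-of-ratios scaling held 77 of 116, quantile normalization 67, no filter 58, no trend 55 and voom 107. With that covariate the counts for caffeine, dextromethorphan, both drugs, interaction and any group were 5, 1, 1, 7 and 16. Without a filter, where more microRNAs are tested, they were 11, 26, 13, 9 and 26. Without a trend the counts for caffeine, dextromethorphan, both drugs and any group were 9, 18, 17 and 26. Caffeine gave 19 calls with median-of-ratios scaling, 18 with quantile normalization, 18 without the erythrocyte list, 48 with voom and 65 in a fit of its own groups. Dextromethorphan gave 29 after thinning, 28 without miR-191a-5p and 25 in a fit of its own groups. Both drugs against dextromethorphan gave 8 after thinning and 0 without DEX2 and DEX3, where 1 dextromethorphan library is assumed to vary like the other groups. The interaction gave 8 with median-of-ratios scaling, 7 with quantile normalization and 11 without miR-191a-5p. Both drugs against caffeine gave 0 in each setting. Leaving out each library in turn gave 4 to 44 calls for caffeine, 12 to 74 for dextromethorphan, 3 to 56 for both drugs, 9 to 24 for both against dextromethorphan, 8 to 38 for the interaction and 18 to 71 for any group; the 56 is without CAFDEX6 and the 9 without DEX2. All 19 list calls were lost with an estimated correlation, 19 held with median-of-ratios scaling, 16 with the haemolysis covariate, 14 after thinning, 13 without a filter, 15 without CAF4 or without DEX1 and 12 without CAFDEX2. Differences of the index, shares of the most abundant microRNAs and correlations between treatments moved by less than their spread (for correlations, a jackknife error of 0.106 to 0.147). Where a library was left out this was nearly fixed in advance, because the spread was computed from those same libraries. It therefore does not show that these values are stable. Depth limits low values: in the shallowest library 1 read was worth 113 FPKM, above the pseudocount of 40. No paired analysis was possible because the column numbers do not match the replicate numbers of the titles. Apart from those numbers, the labels tie no rat to a rat of a different group. Nothing in them therefore says that the groups were paired. Count models, planned only for a file of counts, were not run.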

Other observations

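The test of neighbouring microRNAs was chosen after the results were seen, and the microRNAs named in the next paragraph fall outside the naming rule or were picked after their values were seen.

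miR-183-5p and miR-182, which are co-transcribed in sensory and epithelial cells, rose after dextromethorphan by 1.61 ± 0.37 and 1.37 ± 0.39 log2 units (SE, n = 3 per group, limma adjusted p = 0.0141 and 0.0352). After both drugs they had log2 fold changes of 0.99 and 0.86 and did not pass. The miR-378 family, which is encoded in part within the Ppargc1b gene, rose after dextromethorphan as miR-378a-3p (1.03 ± 0.29), miR-378a-5p (1.07 ± 0.32) and miR-378b (1.48 ± 0.38); these were the only passing members of the drug metabolism regulators apart from miR-27b-3p (1.14 ± 0.29), with miR-378b outside that list. The drug metabolism list as a whole had an adjusted p of 0.96 after dextromethorphan and 0.236 after caffeine. The stress response list had 1, 1 and 2 of 20 members higher after caffeine, dextromethorphan and both drugs and did not pass (adjusted p = 0.341, 0.96 and 0.4), and the let-7 family had no passing member in any comparison with control. The platelet list had 1 of 15 higher after caffeine and after dextromethorphan (miR-199a-3p) and 1 higher and 2 lower after both, and did not pass.

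Picked after their values were seen, miR-122-5p and miR-194-5p, both members of the liver list, differed in opposite directions between dextromethorphan libraries. miR-122-5p was at 6.84e+06 FPKM in DEX1 and at 2.89e+06 and 2.68e+06 in DEX2 and DEX3, whereas miR-194-5p was at 2.91e+04 in DEX1 and at 7.36e+04 and 5.95e+04 in DEX2 and DEX3.

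If fold changes reflect transcripts rather than noise of single microRNAs, neighbours on the chromosome may change alike. Pairs of microRNAs within 10 kb on one strand numbered 276, formed by 240 microRNAs, and include arms of one precursor. Among them the median absolute difference of log2 fold changes after dextromethorphan was 0.4057. The lowest of 10000 random sets of pairs matched on mean level was 0.6107. Reads divided between similar members of 1 cluster would give such a likeness too and were not separated from it. Libraries that differ for a reason other than the drug would also show it, so the likeness does not bear on the drug.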
